A study of Ostrea edulis with 36 samples.

How the data were processed

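Haemocyte RNA of *Ostrea edulis* was measured on 36 one-colour arrays: 30 arrays of single challenged oysters and 6 arrays of control pools, each pool mixed from equal amounts of RNA of 5 unchallenged oysters, per the labels. Groups were stock (Limfjord or Ortigueira), challenge and day after challenge (1, 30 or 90), which makes 12 groups, and were taken from the sample titles. The submitters' processing notes name Agilent Feature Extraction 9.5, and the scanner files give version 9.5.1.1.

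The deposited scanner file of each array holds spot intensities on a linear scale. Per the file headers, Feature Extraction subtracted the local background and removed spatial trends to give the processed intensity, and no normalization between arrays was applied to it. The same deposited files hold the raw mean intensity and the local background of each spot, and flags for spots well above background, saturated spots and outlier spots. The deposited series table holds the authors' own processed intensity on a linear scale. Its values follow the processed intensity of the same spots, and its distributions are nearly the same among the arrays of a stock but differ between the stocks, with column medians of 1096 to 1106 for Limfjord and 1125 to 1129 for Ortigueira, as after quantile normalization of each stock on its own; the authors' method is not given in the sources used here. The direction and centring need no assumption, since the values are single-channel intensities. The authors' table had a blank in 1276 rows of non-control spots, and 6220 probes were used from it, in an alternative only. If it was scaled per stock, as these medians look, stock differences computed from it set levels across separately normalized tables.

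Control spots (536) and outlier-flagged spots (137 over all arrays) were left out, and no spot was saturated. The log2 of the processed intensity minus the array's 75th percentile was averaged over the spots of each distinct probe sequence. The 14034 other spots carried 7017 probe names and 6733 distinct sequences of 55 to 60 nt. Sequences well above background on at least 5 arrays were kept, which dropped 29, and 2 more were dropped because both of their spots were flagged on an array, leaving 6702. No spot had a description and no probe name matched the table of 36649 genes of the RefSeq annotation of assembly xbOstEdul1.1, so no probe was named by gene and no genome position is given. The 20 gene lists that had been fixed could not be applied. A probe well above background on none of the arrays of a group has only a bound there, and where some arrays measured it their number is given and the values of all arrays are used. For a bound, the fold is at least the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own.

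Tests were run with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8) with Benjamini-Hochberg adjustment over the 6702 probes, and a probe passed at an adjusted p under 0.05; all p-values are two-sided. A model with the 12 groups was fitted to all 36 arrays, so that the 24 residual degrees of freedom came from the challenged oysters (prior degrees of freedom 2.13), and a pool was assumed to vary like 1 oyster. From it came the challenge effects (challenged minus pool of the same stock and day, and means of these), the stock differences in response (the effect in Ortigueira minus that in Limfjord), the stock differences among challenged oysters and the time differences. The stock difference over all arrays was fitted with stock, day and challenge as terms and the slide as a random block (correlation -0.0056). Each stock-day was 1 slide, with its control pool at the same array position on each slide. Challenge is therefore compared within slides, while stock and day are compared between them. The slides were scanned on 4 days, with 2 slides on scan day 1 (Limfjord days 1 and 30), 2 on scan day 2 (Limfjord day 90 and Ortigueira day 1) and 1 on each of the others. A model with stock, day and scan day together has more terms than there are slides, so no blocked stock value can be had; within scan day 2 the stocks were on different sampling days.

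The probes named are those fixed by a rule: with no gene names, at most 2 probe IDs per direction and comparison, the largest changes among those that passed and changed the same way in every oyster (each challenged oyster against its pool, or groups that do not overlap). Where none qualified, the smallest p was taken, as for Os1_1263e, Os1_5930e and the decrease of Os1_2834er after challenge, whose samples overlap. Sequences are not given for probes that were high in a single array, since these were not shown to be oyster sequences. The choice of groups, tests, naming rule and alternatives was made before the data were examined, except the alternatives said to have been chosen after it.

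The fits were tested on simulated data for the 6702 probes, with 200 changed by a log2 of 0.585, 1 or 2. Of the probes changed by 2, 92.4% were recovered for the challenge effect over the 6 stock-days, 87.9% for that of Limfjord over the 3 days, 63.6% for Limfjord day 1, 65.2% for the response difference over the 3 days, 87.9% for the stock difference on day 90, 89.4% for Limfjord day 90 minus day 30 and 95.5% for the stock difference over all arrays. Of those changed by 1, the shares were 79.1%, 56.7%, 8.96%, 29.9%, 59.7%, 44.8% and 86.6% in the same order, and the median estimate was 0.910 to 1.05 times the true change over the comparisons and both sizes. The fit over all arrays called more unchanged probes than the threshold allows: over 10 simulations without slide offsets, 12.8% of its calls were false against 5.21% without the block, with an estimated correlation of -0.039. With slide offsets of 0.2 times a probe's SD the shares were 13.2% and 11.1%. The fit was kept as fixed, and the count without the block is given beside it.

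The alternatives were quantile normalization, normexp background correction (offset 50) of the raw intensities, no filter on dim probes, the authors' table, a fit on the compared groups alone, an in-silico pool (the challenged oysters averaged on the linear scale), the slide as a fixed block, no slide block, pools without error, the oyster number as a block, and leaving out each array in turn. Chosen after seeing the data were leaving out both arrays that stood apart, weighting each pool as 5 oysters with and without the in-silico pool, and the 6 slide means. For 12 comparisons of groups of at least 3 arrays, 100 splits of the same arrays were drawn, the real one included.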

Results

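Transcript levels were measured in haemocytes, the circulating blood cells of the European flat oyster *Ostrea edulis*, on 36 one-colour (Cy3) oligonucleotide arrays. The oysters came from 2 stocks. The Limfjord stock was naive to bonamiosis, the disease caused by the haemocyte parasite *Bonamia ostreae*, and the Ortigueira stock came from a bed with a long history of the disease and is described in the labels as the more resistant one. Each challenged oyster had been immersed alone for 24 h with 300000 parasite cells, and haemolymph was drawn 1, 30 or 90 days later. For each stock and day there were 5 challenged oysters on an array each and 1 control pool, made of equal amounts of RNA from 5 unchallenged oysters. That gave 30 arrays of single oysters and 6 arrays of pools. The 75th percentile of spot intensity lay between 1548 and 4606 per array (median 3198), and between 97.0% and 99.97% of the spots of an array were well above background. The number of arrays limits the precision of all comparisons. Levels below are log2 intensities relative to the array's own 75th percentile, so that 0 is that percentile. Duplicate spots of a sequence differed with an SD of 0.034 to 0.065 per array, whereas the median SD between the 5 oysters of a group ran from 0.31 (Limfjord, day 30) to 0.48 (Limfjord, day 1). The files and the reference table paired no probe with a gene, so transcripts are given by probe ID and sequence, without a function.

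The first question was how the haemocytes of the stocks differed over all 36 arrays. Probe Os1_6461e (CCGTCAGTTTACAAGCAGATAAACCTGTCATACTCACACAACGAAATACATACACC) had the largest difference among probes whose arrays did not overlap: its level was -2.96 ± 1.05 (SD, n = 18 arrays) in Ortigueira and -5.89 ± 0.97 (n = 18) in Limfjord, a signal 7.65-fold higher (log2 difference 2.93, SE 0.317, adjusted p = 2.12e-07). It was the only 1 of 6702 tested probes whose stocks did not overlap, with each Ortigueira array above each Limfjord array. By chance 2.20e-08% of splits of 18 against 18 would separate a given probe, in either direction, if arrays were independent. The stocks lay on different slides. With the slides as units, 3 against 3, chance separates the slide values of 10.0% of probes. Separation of all single arrays is stricter and has no chance value by slide here, so it is only descriptive. Probe Os1_1263e (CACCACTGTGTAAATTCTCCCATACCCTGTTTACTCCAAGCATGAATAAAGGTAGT) was 2.44-fold lower in Ortigueira, at -0.48 ± 0.57 against 0.80 ± 0.92 (n = 18 each, SE 0.170, adjusted p = 1.59e-06). Probe Os1_5930e (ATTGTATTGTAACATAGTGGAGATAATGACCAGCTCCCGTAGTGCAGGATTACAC) was 1.77-fold lower, at -1.74 ± 0.39 against -0.92 ± 0.27 (n = 18 each, SE 0.112, adjusted p = 2.27e-06). The arrays of the stocks overlapped for both of these probes. In limma, with day and challenge as terms and the slide as a random block, 771 probes were higher and 704 lower in Ortigueira. The balance turned with the scaling, to 726 higher and 773 lower after quantile normalization and 868 higher and 567 lower in the authors' table. Their median absolute log2 difference was 0.60, and 335 of the 1475 differed over 2-fold. The sign was the same in the challenged oysters of all 3 days for 1369 of the 1475, and the same in the mean of the 3 pool differences for 1450; these arrays were also in the fit, so both counts are descriptive. Each stock-day was a slide of its own, and with the 6 slide means as the samples 203 probes passed (142 higher, 61 lower), 191 of them among the 1475; Os1_6461e passed (adjusted p = 0.0338), while Os1_1263e and Os1_5930e had adjusted p of 0.127 and 0.0782, the highest of 8 alternatives each (lowest 1.54e-06 and 2.24e-06). The count of 1475 is also open to error from the fit itself. In simulated data without slide offsets 12.8% of its calls were false, against 5.21% without the block. With slide offsets of 0.2 times a probe's SD the shares were 13.2% and 11.1%. The estimated correlation there (-0.0078) was nearer the -0.0056 of the real fit. Leaving out the block called 1423 probes here, and that count is open to the same error. The simulations changed 200 of 6702 probes, drawn as independent, so their shares are not the false shares of the 1475 or the 1423.

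**Figure D1:**
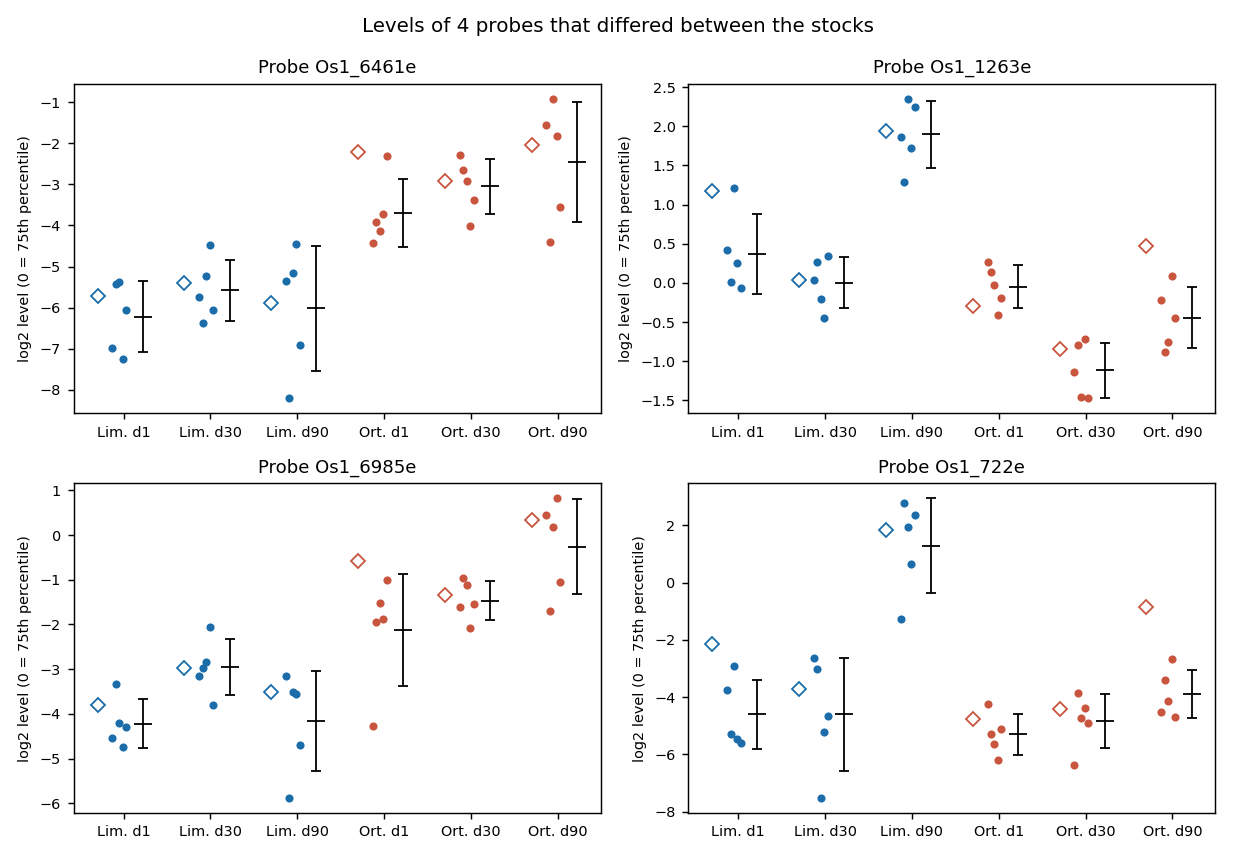
Levels of 4 probes in each array (y axis, log2 relative to the array's 75th percentile) by stock and day (x axis; Lim., Limfjord; Ort., Ortigueira). Filled points are single challenged oysters, open diamonds are control pools of 5 oysters, and bars give the mean ± SD of the 5 challenged oysters; Os1_6461e lay higher in each Ortigueira array than in each Limfjord array, and Os1_722e was at 1.29 ± 1.65 in challenged Limfjord oysters on day 90 against -4.61 ± 1.96 on day 30.

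Among challenged oysters alone, the stocks were then compared within each day, 5 against 5. On day 90, probe Os1_6985e (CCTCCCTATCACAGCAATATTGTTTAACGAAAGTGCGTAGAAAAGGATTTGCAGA) was at -0.26 ± 1.06 in Ortigueira and -4.16 ± 1.13 in Limfjord (n = 5 each), 14.9-fold higher (log2 3.90, SE 0.549, adjusted p = 7.65e-05). Probe Os1_5790e (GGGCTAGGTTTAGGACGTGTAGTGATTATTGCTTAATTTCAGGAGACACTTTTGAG) was 13.3-fold higher (log2 3.73, SE 0.558, adjusted p = 1.30e-04). Lower in Ortigueira on day 90 were Os1_722e (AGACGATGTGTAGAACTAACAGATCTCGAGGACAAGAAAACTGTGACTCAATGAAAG), by 36.1-fold (log2 -5.18, SE 0.790, adjusted p = 1.40e-04), and Os1_635e (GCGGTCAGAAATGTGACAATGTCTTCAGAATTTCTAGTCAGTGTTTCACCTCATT), by 25.5-fold (log2 -4.67, SE 0.820, adjusted p = 7.09e-04). In limma 261 probes were higher and 136 lower in Ortigueira that day. The split was 328 and 186 after quantile normalization, 385 and 139 in the authors' table and 59 and 56 on the arrays of the compared groups alone. The oysters of the stocks did not overlap for 388 of all 6702 tested probes (223 higher, 165 lower in Ortigueira), where chance gives 0.794% if arrays are independent. Each stock was 1 slide that day, so a difference between 2 slides is not excluded by this. Of the 261 higher probes, 223 had the same sign in the challenged oysters of day 1 and 228 in those of day 30, and 205, 191 and 253 in the control pools of days 1, 30 and 90. Of the 136 lower probes, 94 and 114 had the same sign in the challenged oysters of days 1 and 30, and 105, 104 and 114 in the pools of days 1, 30 and 90. The sizes on the other days were smaller, which the choice of probes by their day 90 test alone can give. In challenged oysters the median log2 of the 261 was 1.29 on day 90, 0.52 on day 1 and 0.39 on day 30. That of the 136 was -1.34, -0.18 and -0.34. Likewise, the 58 probes higher on day 1 (below) had a median of 1.81 that day, 0.94 on day 30 and 1.06 on day 90. Medians in the pools, which shared the slides but not the choice, were 0.78, 0.48 and 1.44 (days 1, 30 and 90) for the 261. For the 136 they were -0.64, -0.40 and -0.59. Os1_635e was level on day 1, at -3.82 in Ortigueira and -3.83 in Limfjord, and 68 of the 136 were among the 95 probes that rose in Limfjord from day 30 to day 90 (below). Both lists used the same challenged Limfjord arrays of day 90, so this overlap is no independent agreement. Fitted on the arrays of the compared groups alone, 115 probes passed on day 90, and without Ortigueira oyster 10 the count was 238.

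On day 1, Os1_62er (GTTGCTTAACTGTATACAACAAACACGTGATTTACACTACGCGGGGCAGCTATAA) was 32.7-fold higher in challenged Ortigueira oysters (-1.23 ± 1.50 against -6.26 ± 1.52, n = 5 each, SE 1.21, adjusted p = 0.0405). It was well above background in 4 of the 5 Limfjord oysters. Os1_2924er (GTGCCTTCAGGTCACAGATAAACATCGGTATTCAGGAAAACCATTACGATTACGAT) was 11.3-fold higher (log2 3.50, SE 0.639, adjusted p = 0.0176). Os1_1256e (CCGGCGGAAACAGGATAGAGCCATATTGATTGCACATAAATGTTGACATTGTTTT) and Os1_5358e (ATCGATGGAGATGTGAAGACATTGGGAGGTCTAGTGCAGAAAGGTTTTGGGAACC) were lower, by 2.63-fold and 2.27-fold (adjusted p = 0.0405 and 0.0291). The difference of Os1_62er was a log2 of 3.73 with the other background correction and did not pass (adjusted p = 0.0641; 0.0408 to 0.111 over its 5 alternatives). In the day 1 control pools, 55 of the 58 higher and 18 of the 25 lower probes of that day had the same sign as in the challenged oysters. Of these 4 named probes, Os1_1256e kept its order in the pools (-0.33 in Ortigueira, 0.32 in Limfjord). The order was the opposite for Os1_62er (-3.08 and -1.86), Os1_2924er (-0.61 and 0.44) and Os1_5358e (1.31 and -0.17). In all, 58 probes were higher and 25 lower; the split was 43 and 31 after quantile normalization and 42 and 9 in the authors' table. On day 30, 1 probe passed: Os1_3541er (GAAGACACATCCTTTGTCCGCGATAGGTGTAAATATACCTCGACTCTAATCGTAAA), 3.58-fold lower in Ortigueira (-3.10 ± 0.60 against -1.26 ± 0.25, n = 5 each, adjusted p = 0.0354), with 745 probes at an unadjusted p under 0.05 where chance gives 335.1. Days 1 and 90 shared 33 probes, 32 with the same sign, where independent lists of these sizes would share 4.92. The stock differences correlated across all probes between days, with r = 0.361 for days 1 and 30, 0.461 for days 1 and 90 and 0.467 for days 30 and 90; probes are not independent replicates. Whether a stock difference changed between days was not tested. The day 1 count fell to 0 without Ortigueira oyster 17 and when fitted on the compared groups alone, and rose to 195 without Limfjord oyster 14; the day 30 probe was lost with the other background correction (adjusted p = 0.0585, the highest of 5 alternatives; lowest 0.0249), and the day 30 count was 15 on the compared groups alone and ran from 0 to 4 with an array left out (0 without Limfjord oyster 4, 4 without Ortigueira oyster 17).

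The time course after challenge was followed within each stock. In Limfjord, a group of probes rose from day 30 to day 90. Os1_635e went from -4.11 ± 1.60 to 2.13 ± 0.50 (n = 5 each), 76.0-fold higher (log2 6.25, SE 0.820, adjusted p = 2.16e-05), and Os1_2834er (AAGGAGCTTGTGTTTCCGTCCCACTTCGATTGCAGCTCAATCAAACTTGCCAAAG) from -3.82 ± 1.13 to 2.09 ± 0.75, 60.2-fold higher (log2 5.91, SE 0.522, adjusted p = 4.59e-08). Os1_4147e (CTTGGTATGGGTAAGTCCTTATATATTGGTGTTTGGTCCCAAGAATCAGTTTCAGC) and Os1_2783e (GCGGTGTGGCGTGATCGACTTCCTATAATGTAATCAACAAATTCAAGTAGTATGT) fell, by 2.37-fold and 2.30-fold (adjusted p = 0.0175 and 0.0171). In limma 95 probes rose and 12 fell; the split was 108 and 32 after quantile normalization, 104 and 31 in the authors' table and 75 and 23 without 2 arrays that stood apart (below). Of the 95, 40 rose over 4-fold. Their median level per array was 1.33 ± 0.37 (SD, n = 5) in challenged Limfjord oysters on day 90, against -2.22 ± 0.37 on day 30 and -2.21 ± 0.20 on day 1. The unchallenged pool of Limfjord moved with them, from -1.54 on day 30 to 1.54 on day 90, with all 40 probes higher and a median log2 difference of 2.59. In the Ortigueira pools the 40 probes were also all higher on day 90 than on day 30, with a median log2 difference of 2.24. The challenged Ortigueira oysters were at -1.59 ± 0.48 on day 90 and -2.77 ± 0.45 on day 30 (n = 5 each). Day and slide cannot be told apart in these comparisons, and with 1 pool per stock-day the changes in the pools have no replicate check.

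**Figure D2:**
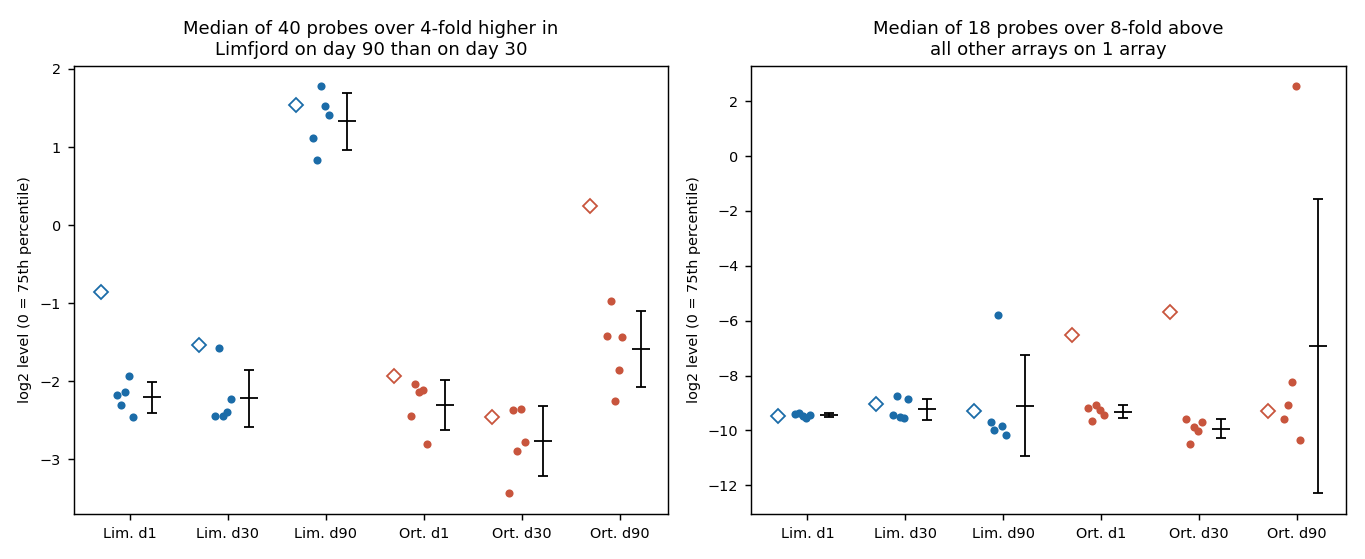
Left, the median level (y axis, log2 relative to the array's 75th percentile) of the 40 probes that rose over 4-fold in challenged Limfjord oysters from day 30 to day 90, per array, by stock and day (x axis; Lim., Limfjord; Ort., Ortigueira): the day 90 pools of both stocks, at 1.54 and 0.25, lay above their day 30 pools, at -1.54 and -2.46. Right, the median level of the 18 probes that were over 8-fold higher in 1 array than in all others: 2.55 in oyster 13 of Ortigueira, day 90, and -5.68 in the Ortigueira day 30 pool. Filled points are challenged oysters, open diamonds are control pools, and bars give the mean ± SD of the 5 oysters.

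From day 1 to day 30 no probe passed in Limfjord, with 707 at an unadjusted p under 0.05 in limma; the smallest p in each direction belonged to Os1_1533e (log2 1.07) and Os1_1266er (log2 -1.20), both with an adjusted p of 0.0643. The count was 7 with the other background correction and 52 without Limfjord day 1 oyster 20. In Ortigueira 1 probe rose in that interval, Os1_6285er (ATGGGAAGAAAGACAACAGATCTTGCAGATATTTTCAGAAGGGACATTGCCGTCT), from -1.98 ± 0.25 to -1.11 ± 0.19 (n = 5 each), 1.82-fold higher (SE 0.144, adjusted p = 0.0148). From day 30 to day 90 in Ortigueira, Os1_1746er (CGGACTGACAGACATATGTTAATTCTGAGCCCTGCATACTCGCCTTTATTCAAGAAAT) rose 2.26-fold and Os1_1382er (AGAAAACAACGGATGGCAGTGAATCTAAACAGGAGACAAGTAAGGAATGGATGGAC) 2.23-fold (log2 1.17 and 1.16, SE 0.221 and 0.217, adjusted p = 0.0479 for both). Unadjusted p under 0.05 held for 683 and 739 probes in the Ortigueira intervals. Neither interval's calls in Ortigueira held when fitted on the compared groups alone (0 probes each), and with an array left out their counts ran from 0 (without day 1 oyster 2; without day 30 oyster 5) to 6 (without day 1 oyster 6) and 4 (without day 90 oyster 15).

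The effect of the challenge was the difference between the 5 challenged oysters and the control pool of the same slide. Averaged over the 6 stock-days, Os1_2834er was lower in challenged oysters, at -2.91 ± 2.49 (n = 30 oysters) against -0.73 ± 2.29 (n = 6 pools), 4.54-fold (log2 -2.18, SE 0.369, adjusted p = 0.0198). It lay below the pool of its slide in 28 of 30 oysters, but did not pass in 4 of 36 fits with an array left out, each time a control pool. The 5 oysters of a slide share 1 pool, so such counts of oysters rest on 6 pools, or 3 within a stock. No probe was higher; the smallest p belonged to Os1_6011er (log2 0.49, SE 0.117, adjusted p = 0.477), which lay above its pool in 27 of 30 oysters. In Limfjord over the 3 days, Os1_5688er (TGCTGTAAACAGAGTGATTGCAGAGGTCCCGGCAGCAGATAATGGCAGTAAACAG) was 1.75-fold higher after challenge, at -0.12 ± 0.25 (n = 15) against -0.93 ± 0.20 (n = 3 pools; SE 0.139, adjusted p = 0.0270), in 15 of 15 oysters. It did not pass on the compared groups alone (adjusted p = 0.381, the highest of 9 alternatives; lowest 8.83e-07) or in the authors' table (0.0599). In Ortigueira over the 3 days no probe passed in limma, with 156 at an unadjusted p under 0.05; Os1_121er (log2 0.73) and Os1_1961er (log2 -0.88) had the smallest p in each direction, both with an adjusted p of 1.00. The test takes a pool to vary like 1 oyster although it averages 5, and unadjusted p-values under 0.05 were fewer than chance gives (220, 295 and 156 against 335.1 for the 6 stock-days, Limfjord and Ortigueira); weighting each pool as 5 oysters, an alternative chosen after seeing the data, gave 250, 369 and 101 probes. The call of Os1_2834er ended when the challenged oysters were averaged on the linear scale as the pools were (log2 -1.98, adjusted p = 0.0813, the highest of 10 alternatives; lowest 7.88e-07), and quantile normalization gave 44 probes over the 6 stock-days (43 higher, 1 lower) and 29 in Limfjord (28 higher, 1 lower).

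By single day, 2 probes passed in Limfjord on day 1, Os1_3227e and Os1_6636er. Their levels were -9.05 ± 0.74 and -8.10 ± 0.87 in the challenged oysters (n = 5), of which 2 were well above background for either probe, and -0.04 and -0.85 in the pool (fitted log2 -9.0 and -7.26, adjusted p = 1.13e-04 and 1.89e-04). Most of the challenged oysters were at background for them, so these fitted values are not measured sizes. Both probes were over 8-fold higher in that pool than in any of the other 35 arrays. On day 1 in Ortigueira, Os1_3018er was 4.05-fold lower after challenge, at -1.40 ± 0.36 (n = 5) against 0.62 in the pool (SE 0.360, adjusted p = 0.0450), in 5 of 5 oysters. The other 5 pools lay between -1.78 and -1.08, near the challenged oysters, so that this value too came from 1 pool that stood apart. It did not pass in 4 of the 5 fits with an oyster left out. On days 30 and 90 no probe passed in limma in either stock, with 23 and 274 probes at an unadjusted p under 0.05 in Limfjord and 13 and 78 in Ortigueira. The smallest adjusted p on those days was that of Os1_3092er in Limfjord on day 90 (log2 1.64, adjusted p = 0.328). In Ortigueira on day 30, Os1_610e was not well above background in any of 5 challenged oysters and was at least 79.3-fold higher in the pool, with an adjusted p of 1.00. It was also at -3.92 in the Ortigueira day 1 pool and at 5.54 in Ortigueira day 90 oyster 13, the array with the set of 18 probes given below. Fitted on the compared groups alone its adjusted p was 6.75e-04, the lowest of 7 alternatives (highest 1.00), and 6 probes passed. Each single-day value rests on 1 pool, and on the compared groups alone Os1_3227e, Os1_6636er and Os1_3018er did not pass (adjusted p = 0.0528, 0.223 and 0.647, the highest of 7, 7 and 8 alternatives; lowest 2.60e-10, 2.20e-09 and 2.47e-06). In the authors' table no probe passed on day 1 in either stock, with Os1_3018er at an adjusted p of 0.0695 and the other 2 not usable because of blanks. Weighting each pool as 5 oysters gave 431 probes in Limfjord on day 1, 330 on day 90, 41 in Ortigueira on day 1, 55 on day 90 and 0 on day 30 in both stocks.

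**Figure D3:**
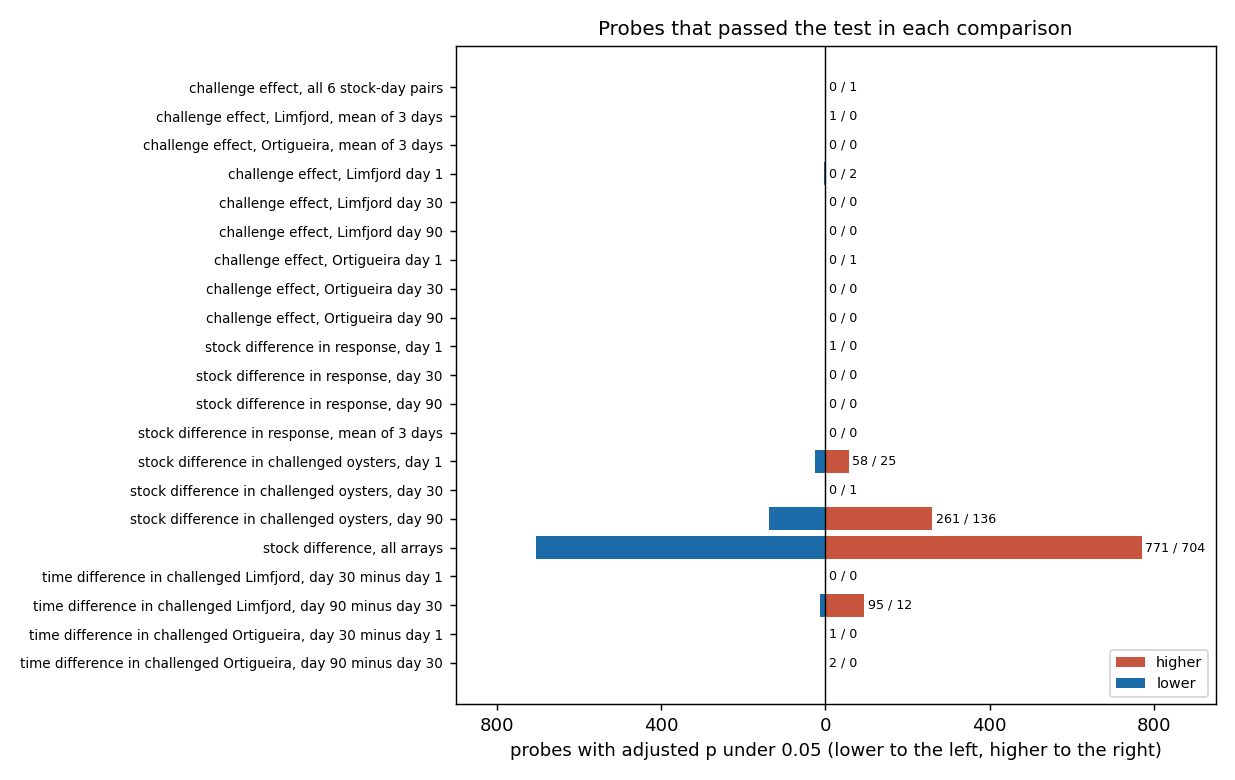
Number of the 6702 tested probes with an adjusted p under 0.05 in each of the 21 comparisons (y axis); bars run right from 0 for higher and left for lower probes (x axis, number of probes). The stock difference over all arrays had 771 higher and 704 lower probes, and 20 comparisons had between 0 and 397 in all.

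The series asks how the stocks differed in their response, which is the challenge effect in Ortigueira minus that in Limfjord. On day 1, 1 probe passed, Os1_3227e (adjusted p = 0.0180). It was well above background in none of the 6 Ortigueira arrays of that day, so that Ortigueira gave no measurable effect, and in 3 of the 6 Limfjord arrays. The call rests on the Limfjord day 1 pool alone, at -0.04, and no size of a stock difference in response can be read from it. Os1_5358e had the smallest p among lower probes that day, with an effect of -0.69 in Ortigueira and 1.98 in Limfjord (log2 -2.66, SE 0.638, adjusted p = 0.476). On days 30 and 90 and over the 3 days no probe passed in limma, with 20, 155 and 242 at an unadjusted p under 0.05. Over the 3 days Os1_1961er was nearest, with an effect of -0.88 in Ortigueira and 0.49 in Limfjord (log2 -1.36, SE 0.307, adjusted p = 0.975). It passed in the authors' table (log2 -1.37, adjusted p = 0.0249), without 2 arrays that stood apart (log2 -1.34, adjusted p = 0.0429) and in the alternatives that shrink the error of the pools. Its adjusted p ran from 2.25e-07 to 0.996 over 10 alternatives. The median SE was 0.623 for a single day and 0.360 for the mean of days, so that differences of 2-fold on a single day were within 2 SE for a typical probe. When the pools were taken as free of error 2248, 191, 1016 and 1662 probes passed on days 1, 30 and 90 and over the 3 days, and weighting each pool as 5 oysters gave 690, 0, 134 and 283.

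A pair of arrays stood apart from the others of their group. In Ortigueira on day 90, oyster 13 had 18 probes over 8-fold above all other 35 arrays, with a median level of 2.55, while the next array was the Ortigueira day 30 control pool at -5.68. In Limfjord on day 90, oyster 9 had 99.97% of its spots well above background, against 98.3% to 98.5% in the other 4 oysters, and the lowest percentile of its levels ended at -5.93 rather than between -8.98 and -8.52. Without both arrays, 373 probes differed between the stocks on day 90, 281 of them among the 397 called with all arrays, and 1353 over all arrays. The challenge effect then had 9 probes over the 6 stock-days and 11 in Ortigueira over the 3 days, all lower. The difference in response over the 3 days had 9, also all lower. The 18 probes were also raised in the Ortigueira day 1 pool (median -6.52) and day 30 pool, against -9.28 in the Ortigueira day 90 pool. Lower calls of these probes made without oyster 13 can therefore come from what these pools held. None of the lower calls made without both arrays is read here as an effect of the challenge. Os1_2834er, which passed over the 6 stock-days, and Os1_1961er, which passed for the response, were not among the 18. Whether the other probes called were among them was not examined.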

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

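The tests in this part were chosen after the results were seen, except the scan-day test. Of 90 groups of 5 oysters examined for a value far from the rest, 10 held one (a gap to the nearest value over 0.71 of the range). Chance flags about 1 in 20 groups of unselected, independent values; here several values came from the same array and 1 measure is the median of probes picked for being high in 1 oyster, so the 10 have no such chance value to be set against.

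The share of spots well above background stood apart at 97.5% in Limfjord day 30 oyster 5, at 99.97% in Limfjord day 90 oyster 9 and at 99.2% in Ortigueira day 90 oyster 13. The level at the 1st percentile of the array stood apart at -5.93 in Limfjord day 90 oyster 9 and at -9.01 in Ortigueira day 90 oyster 15. The median of the 18 probes described below stood apart at -5.80 in Limfjord day 90 oyster 9 and at 2.55 in Ortigueira day 90 oyster 13. Among named probes, Os1_5358e was low at 1.29 in Limfjord day 1 oyster 9 (the others 1.82 to 2.00), Os1_635e was high at 3.00 in Limfjord day 90 oyster 9 (the others 1.70 to 2.00) and Os1_1746er was high at -2.21 in Ortigueira day 90 oyster 10 (the others -3.66 to -3.32). The fitted stock difference in response of Os1_3227e on day 1 was a log2 of 9.48, which is no measured size, since no Ortigueira array of that day was well above background and the value rests on the Limfjord day 1 pool alone.

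The 18 probes over 8-fold above all other arrays in Ortigueira day 90 oyster 13 are the first pattern weighed. A local fault of spots on that array is argued against by the duplicate spots of these probes, which lie apart on the array and differed with a median SD of 0.061. Duplicate spots met the same labelled RNA, so they do not speak to a fault that reached the whole array or its RNA. RNA of 1 further source, present also in the Ortigueira day 30 pool, is a candidate explanation: across the 17 probes above background there, the levels on both arrays correlated with r = 0.982 (rho 0.958), and their difference of 8.10 varied with an SD of 0.41 against 2.02 for the levels. In the Ortigueira day 1 pool r was 0.914 over 14 probes, in challenged Ortigueira day 90 oyster 12 it was 0.846 over the 18 probes (11 well above background), and in Limfjord day 90 oyster 9, where dim probes were raised throughout, it was -0.158. What the source is (another organism, the challenge parasite included, or another kind of oyster cell) was not tested; the profile was seen in challenged oysters and in pools of unchallenged ones.

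The second pattern is that the challenge effects of the 6 slides were weakly correlated across probes, with a mean of 0.147 over the 15 slide pairs (-0.031 to 0.259). The control RNA was pooled before labelling, so that a pool's log level is that of a mean, which exceeds the mean of log levels where oysters vary. This fits the data: the challenge effect fell with that gap, taken from the challenged oysters of the other 5 slides, with a mean slope of -0.750 and negative slopes on each slide (-0.511 to -1.10). With the challenged oysters pooled in silico the mean correlation was -0.00306, so that on average no common direction was left. Oysters at the other array positions, taken as controls, gave means of -0.052 to 0.037. The pairs pooled in silico still ran from -0.215 to 0.174, a range that holds the 0.147. The mean therefore does not decide against the pool's fixed array position as a cause. Nor does the same mean correlation decide against a response to the parasite common to the slides, and one of single probes or slides also stays open.

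The third pattern is the stock difference, which the design places between slides. Offsets of single slides are argued against, since the differences of 2 days, from different slides, correlated across probes with r of at least 0.361; the Limfjord slides of days 1 and 30 shared a scan day, while the slides of days 30 and 90, with r = 0.467, shared none. Scan day is argued against as the whole cause, since the difference between the 2 slides of 1 scan day correlated with that of the other 4 slides with r = 0.385. The origin of the stocks, and any handling that all slides of a stock shared, such as the labelling of their RNA, stay open and cannot be separated by these data.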

How the results depend on the processing

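Of 164 counts recomputed under settings other than leaving out single arrays, 100 stayed within 1.5 times the reported count and 64 did not. Counts of 0 that stayed 0 are among the 100, so the share is no measure of how stable the calls were. For the stock difference over all arrays, the fit on the compared groups was the main fit itself. No named probe changed sign. The balance of higher and lower calls turned in some: the stock difference over all arrays had 726 higher and 773 lower with quantile normalization, which also gave 43 higher and 1 lower for the challenge over the 6 stock-days and 4 and 2 for Limfjord on day 1, and the stocks on day 30 had 11 higher and 4 lower on the compared groups alone. The causes were not tested unless given. The stock difference over all arrays, that on day 90 and the Limfjord change from day 30 to day 90 kept counts within 1.5 times under quantile normalization (1499, 514, 140), normexp (1455, 441, 121), no filter (1476, 397, 107) and the authors' table (1435, 524, 135), with 1395, 395 and 105 probes shared under quantile normalization. The challenge and response counts of single days rest on 1 pool per stock, and those over the 3 days or the 6 stock-days on 3 pools per stock. At least 97.0% of the spots of each array were well above background, but it limited the sizes of single results, such as those of Os1_3227e, Os1_6636er and Os1_610e.

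With quantile normalization the challenge effect had 44 probes over the 6 stock-days, 29 in Limfjord over the 3 days, 1 in Ortigueira over the 3 days, 6 in Limfjord on day 1 and 0 in Ortigueira on day 1, and the response on day 1 had 3. With normexp these were 2 over the 6 stock-days, 2 in Limfjord, 5 in Limfjord on day 1 and 2 in the day 1 response, with 0 for the stocks on day 30, 7 for Limfjord day 30 minus day 1 and 0 for Ortigueira day 90 minus day 30. In the authors' table (6220 probes) there were 0 for Limfjord over the 3 days, Limfjord day 1, Ortigueira day 1 and the day 1 response, 1 for the response over the 3 days, 51 for the stocks on day 1 and 4 for Ortigueira day 90 minus day 30. On the arrays of the compared groups alone, where fewer oysters give the spread, the challenge effect had 0 in Limfjord over the 3 days, 0 and 3 in Limfjord on days 1 and 30, and 2 and 6 in Ortigueira on days 1 and 30. In that setting the response had 5 on day 1 and 3 on day 30, the stocks differed at 0, 15 and 115 probes on days 1, 30 and 90, and both Ortigueira time intervals had 0. With the in-silico pool the challenge effect had 0 over the 6 stock-days and 0 in Ortigueira on day 1. With pools taken as free of error, which removes their share of the variance by construction, the response had 2248, 191, 1016 and 1662 on days 1, 30 and 90 and over the 3 days. Without the slide block the stock difference had 1423 probes.

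Chosen after seeing the data, leaving out both arrays that stood apart gave 9 for the challenge over the 6 stock-days, 11 for Ortigueira over the 3 days, 9 for the response over the 3 days and 0 for Ortigueira day 90 minus day 30. Weighting each pool as 5 oysters, which shrinks its error by construction, gave 250, 369 and 101 for the challenge over the 6 stock-days, Limfjord and Ortigueira, 431 and 330 for Limfjord on days 1 and 90, 41 and 55 for Ortigueira on days 1 and 90, and 690, 134 and 283 for the response on days 1 and 90 and over the 3 days. With the in-silico pool added these were 232, 403, 107, 519, 445, 70, 78, 681, 155 and 290 in the same order. The 6 slide means, with 3 per stock, gave 203 for the stock difference.

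Leaving out each array in turn gave 0 to 1 for the challenge over the 6 stock-days (0 without the Limfjord day 1 pool), 0 to 3 in Limfjord over the 3 days (0 without the day 1 pool, 3 without the day 30 pool), 0 to 6 in Ortigueira over the 3 days (6 without day 90 oyster 13), 2 to 5 in Limfjord on day 1 (5 without oyster 3) and 0 to 1 in Ortigueira on day 1 (0 in 4 of 5 fits, without oyster 2 among others). It gave 0 throughout for the challenge on days 30 and 90 in both stocks and for the response on days 30 and 90 and over the 3 days, and 1 to 2 for the response on day 1 (2 without Limfjord oyster 3). Stock counts ran from 0 to 195 on day 1, 0 to 4 on day 30, 238 to 418 on day 90 and 1212 to 1542 over all arrays. Time counts ran from 0 to 52 and 83 to 134 in Limfjord, and from 0 to 6 and 0 to 4 in Ortigueira.

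The alternatives for the 20 gene lists were not run, because no probe had a gene name. The data did not show that the oyster numbers in the titles pair the samples, and whether the same oysters were bled on several days stays open. Deviations from the group means were compared across probes. Between days 1 and 30 the shared numbers 14 and 20 of Limfjord correlated at -0.0083 and -0.016. The numbers 5, 6 and 17 of Ortigueira correlated at -0.059, 0.079 and -0.320. Number 9 of Limfjord, shared by days 1 and 90, correlated at 0.090. None was its partner's best match. With the number as a replicate block, day 30 minus day 1 had 0 probes in Limfjord and 0 in Ortigueira, against 0 and 1.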

Other observations

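The tests in this part were chosen after the data were seen, except the splits of the arrays.

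Some probes took one of 2 separate levels among the 30 challenged oysters. With a gap of over 4 on the log2 scale (16-fold) and at least 3 oysters on each side, limits set after the data were seen, there were 30 such probes. For Os1_5834e 14 oysters were low and 16 high. Os1_939er and Os1_798er split the oysters in the same way, with 5 low and 25 high, and the other probes each split them differently, so that there were 29 patterns. Low oysters came from both stocks for 29 of the 30 probes, and a median of 5 of the 6 stock-days held both levels. Of the 354 low values, 268 were not well above background, so the gaps are not measured folds. All 6 control pools lay above the gap for 18 of the probes. A pool mixes RNA of 5 oysters, so any high oyster in it raises the level of the pool. The pools therefore cannot show whether low oysters were among the unchallenged ones. No difference between the stocks in the number of low oysters passed Fisher's exact test (smallest adjusted p = 0.19 over the 30 probes). No explanation was tested for them.

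The 40 probes that rose over 4-fold in challenged Limfjord oysters by day 90 were, in Ortigueira on day 90, lower in challenged oysters than in their pool for 38 of 40, with a median log2 of -1.69. In Limfjord on day 90, 24 of 40 were lower than in the pool, with a median log2 of -0.20. The set's median level was higher in the pool on the other days too. In Limfjord it was -0.85 in the pool against -2.21 (mean of 5 oysters) on day 1, and -1.54 against -2.22 on day 30. In Ortigueira it was -1.93 against -2.31 on day 1 and -2.46 against -2.77 on day 30. A level below the pool was thus not particular to Ortigueira on day 90, and pooling before labelling can add to it (above). This set was picked for its level in the Limfjord oysters, the difference was not tested, and each side rests on 1 pool.

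Other splits of the same arrays were drawn 100 times for each of 12 comparisons, the real one included. As many probes as in the real split passed in 1 split for the stock difference over all arrays (1475; highest other 5), in 1 for the stocks on day 90 (397; highest other 117) and in 1 for Limfjord day 90 minus day 30 (107; highest other 4), so chance in which single arrays fell in which group can be excluded for these. For the stocks on days 1 and 30, 3 splits each gave as many (83, highest other 317; 1, highest other 1), under the same limit of 5 in 100. The day 1 count was nevertheless 0 without Ortigueira oyster 17, and the day 30 count moved in 9 of 10 fits with an array left out. These splits mix arrays of different slides, and each stock-day was 1 slide, so they do not exclude chance differences between slides; by slide there are 3 per stock, or 1 per group within a day or time interval, too few for a test by splits. The split with 317 calls, several times the real count, points to a structure of the day 1 samples, which was not examined. Chance cannot be excluded for Ortigueira day 30 minus day 1 (8 splits; real 1, highest other 2) or Ortigueira day 90 minus day 30 (7 splits; real 2, highest other 178). Nor is chance excluded for the challenge effect, where the splits do not decide. As many probes passed in 80 splits over the 6 stock-days (real 1, highest other 144) and in 84 in Limfjord (real 1, highest other 971). These splits put any 1 array of a slide, mostly that of a single oyster, in the place of the pool. A pool averages 5 oysters, so it cannot be exchanged with 1 oyster. Where the real count was 0 all 100 splits reach it, so they show nothing about chance: Limfjord day 30 minus day 1 (highest other 54), the challenge effect in Ortigueira (105) and the response over the 3 days (212). In the challenge and response comparisons some splits called over 100 probes. Single oysters stood in for pools there, so these counts cannot be set against the real ones. Over 100 calls in a split of the last Ortigueira interval point to a structure of the samples. What it is, a single array that stands apart included, was not examined.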
